A study of Mus musculus with 12 samples.

How the data were processed

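Total RNA was extracted with Trizol from mouse peritoneal macrophages kept in RPMI medium with 10% serum, and 12 libraries were sequenced on an Illumina instrument, per the labels' protocols. The libraries fall into 4 groups of 3: untreated control, interferon gamma (IFN-γ), Remodelin hydrobromide, and Remodelin with IFN-γ. Groups and replicate numbers came from the sample titles. The labels used here give no dose, time, animal, batch or day, and nothing in them says that the 3 libraries of a group came from separate cultures or animals. All p-values therefore measure only the spread between these libraries, which may be technical.

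The authors' deposited table holds raw read counts per gene for each library, per the file headers, with 55586 genes. CASAVA 1.8, HISAT2 2.0.5 and featureCounts 1.5.0-p3 are named in the submitters' processing notes, which give them no order or role. The genome build, the annotation release, the strand setting of the counting and the handling of reads that match several genes are not given in the sources used here. Coordinates in the table matched those of the GRCm38 annotation (GENCODE M21) for 1494 of 52081 shared gene identifiers, so no coordinates are printed. The table includes 172 loci without a standard identifier, of which 111 passed the count filter. Genes with near-identical copies, such as tubulins and histocompatibility genes, and genes that overlap on opposite strands are uncertain, since the counting could divide or merge their reads.

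The authors' deposited table also holds FPKM values, which were checked against the counts and not tested. For genes with over 100 reads, counts divided by gene length gave 1 constant per library, and the implied library denominator was 0.954 to 1.02 times the TMM-scaled total. The authors' deposited log2 fold changes and p-values of their own comparisons were read for a side-by-side count only, and the means per group that stand beside them were not used here. The tool behind those comparisons is not given in the sources used here.

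Library totals ran from 15917454 to 19418665 counts, and a floor of 3 counts corresponded to 0.154 to 0.188 CPM, the read count scaled to the library total. That floor covers counting error only, since reads without molecular identifiers are not independent molecules. Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalisation and the default count filter by group, which kept 13474 genes. All 12 libraries entered 1 fit with a mean per group, so that comparisons shared 1 estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. The common biological coefficient of variation was 18.6%. Values after ± are SE for fold changes and SD for CPM, with n = 3 libraries per group, and log2 CPM used a prior count of 2.

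Before the data were examined, 4 comparisons between groups, their interaction, an average IFN-γ effect for choosing IFN-γ-responsive genes, 40 gene lists and a rule for naming genes were fixed. The lists covered interferon responses, antigen presentation, macrophage states, stress, metabolism and markers of other peritoneal cells, and 38 of them had at least 5 tested genes. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 between genes, and with an estimated correlation as an alternative, and p-values were adjusted over the 38 lists. The naming rule took up to 8 genes in each direction with the most extreme fold changes among called genes with a mean CPM of at least 5, groups that did not overlap and an established symbol. It added up to 4 genes per described list with the smallest p, and 12 genes fixed in advance, and some genes that it names are not reported here. The average Remodelin effect over both levels of IFN-γ was added after seeing that the interaction called 1 gene, and the naming rule was applied to it as well.

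The test was checked on simulated counts with 200 genes changed by known amounts. Of 2-fold changes it recovered 41.8% for IFN-γ against control, 50.7% for Remodelin against control, 64.2% for Remodelin with IFN-γ against IFN-γ, 16.4% for the interaction and 83.6% for the average Remodelin effect. False calls were 5 of 98, 11 of 106, 5 of 111, 7 of 55 and 7 of 151 calls in the same order. The simulated libraries held no trends with GC content or transcript length, so the check is more favourable than the data. Alternatives fixed in advance were DESeq2 size factors within edgeR, no count filter, a filter of 50 reads in 3 libraries, DESeq2 1.42.0, limma-voom, a block on replicate number, the 2 compared groups alone and each library left out in turn. Alternatives chosen after seeing the data were removal of the trend of each library with GC content, removal of trends with GC content and transcript length, leaving out 1 library of each of 2 groups together, and, for the lists, leaving out each library in turn. GC content and transcript length came from the longest transcript of each gene in GENCODE M21, matched by identifier, and were known for 99.0% of tested genes. Principal components used the 1000 most variable tested genes.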

Results

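Gene expression was measured by RNA sequencing in mouse peritoneal macrophages, the resident phagocytes of the abdominal cavity, under 4 conditions with 3 libraries each. Cells were untreated, given IFN-γ, the classical activating cytokine of macrophages, given Remodelin, or given both. Remodelin is an inhibitor of the acetyltransferase NAT10, the enzyme that writes N4-acetylcytidine (ac4C) in RNA, and the series concerns loss of this mark in macrophages of liver cancer. Libraries held 15917454 to 19418665 counts, and 17353 to 18175 genes were detected in each. The first principal component took 23.5% of the variance, with all 6 Remodelin libraries on the positive side (5.91 to 16.9) and the other 6 on the negative side (-15.8 to -6.93). This axis partly follows a trend of the libraries with GC content. Spearman correlations of library deviations with GC content were 0.534 and 0.55 for control 2 and 3, the lowest on the component. For Remodelin with IFN-γ 1, the highest, the value was -0.69. Remodelin 1 and 2 (0.264 and 0.0963) and IFN-γ 3 (-0.168) had the opposite sign to that order. The component thus does not part treatment from this trend. Nat10 itself, the target of the inhibitor, was at 18.1 ± 1.97 CPM in control and 17.7 ± 4.28 CPM in Remodelin libraries, and its log2 fold change was -0.03 ± 0.21.

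With Remodelin and no IFN-γ, Upk3b, a membrane protein of mesothelium, fell from 46.5 ± 11.2 to 11.4 ± 0.162 CPM (log2 fold change -2.03 ± 0.19, adjusted p = 8.22e-05, edgeR quasi-likelihood). The chitinase-like gene Chil1 fell by 2.75 ± 0.36 on the log2 scale, the protease inhibitor Serpina3g by 1.96 ± 0.28, the calcification inhibitor Mgp by 1.75 ± 0.20 and the lipid transporter Spns2 by 1.42 ± 0.22. Cox6a2, a cytochrome c oxidase subunit, rose by 2.07 ± 0.24 and the angiogenic factor Vegfa by 1.05 ± 0.17. The mitochondrial transfer RNA gene mt-Tp rose by 2.44 ± 0.32. In all, 26 genes were higher and 88 lower, and 77.2% of calls were lower. That split moved with the processing, from 66.8% lower of 190 calls after removal of the GC trend to 58.3% lower of 408 calls after removal of GC and length trends, both chosen after seeing the data. With no filter on low counts it was even, at 141 higher and 142 lower. DESeq2 called 267 genes, 93 higher and 174 lower. Without both control 1 and Remodelin 1, also chosen after seeing the data, the count was 1853, with 1024 higher and 829 lower, and 107 of the 114 were among them. Without control 2 the count was 20, without control 3 it was 53, without Remodelin 2 it was 38 and without Remodelin 3 it was 36. Of 40 named genes called here, 10 kept the call in every fit without 1 library, among them the 8 above and the desaturase Fads2 (-1.07 ± 0.18). The others lost it in at least 1 fit. Losses numbered 30 without control 2, 27 without Remodelin 3, 24 without Remodelin 2, 16 without control 1, 14 without control 3 and 11 without Remodelin 1, with adjusted p up to 0.226, 0.196, 0.148, 0.0954, 0.153 and 0.0924, and no gene changed direction.

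**Figure D1:**
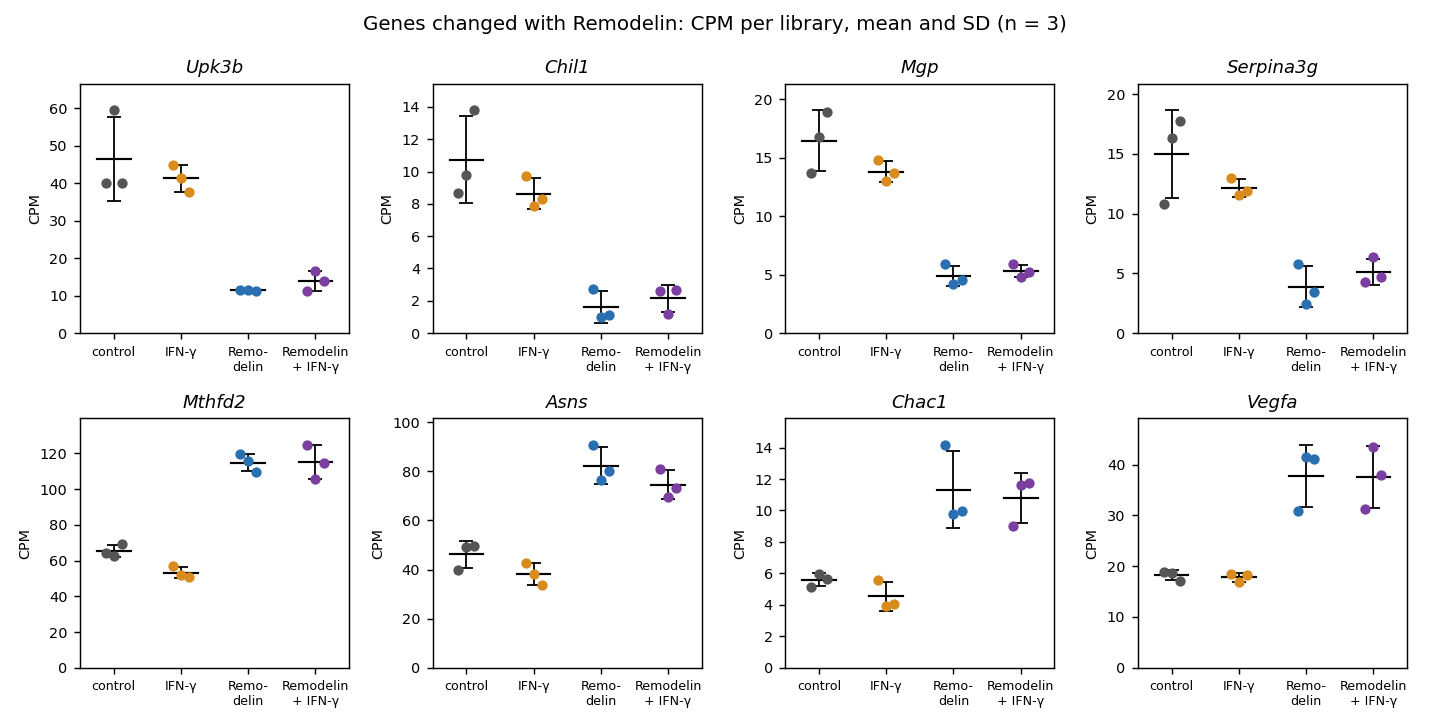
CPM of 8 genes in each library (points), by group on the horizontal axis, with the mean and SD of 3 libraries (black). Upk3b was at 46.5 CPM in control and 11.4 CPM in Remodelin libraries, and Mthfd2 at 65.3 and 115 CPM.

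Cholesterol synthesis genes fell together with Remodelin. Of 25 tested, 6 were lower and 0 higher, and 18 were lower adjusted over the list alone, with a median log2 fold change of -0.63 (camera adjusted p = 6.85e-17, and adjusted p = 0.000382 with an estimated correlation). Acat2 was at -1.09 ± 0.19, the lanosterol demethylase Cyp51 at -0.74 ± 0.15 and the sterol sensor Insig1 at -0.70 ± 0.14. Cell cycle genes fell as a list, with a median of -0.48, 1 of 24 called and 13 lower adjusted over the list alone (adjusted p = 3.22e-10, and adjusted p = 0.00136 with an estimated correlation). The helicase subunit Mcm5 was at -1.04 ± 0.18. Genes of the integrated stress response, the programme driven by the transcription factor ATF4, had a median of 0.51, with 7 of 23 higher and 12 adjusted over the list alone (adjusted p = 4.42e-10). That call was lost with the other setting (adjusted p = 0.0595 with an estimated correlation). Its members included the folate enzyme Mthfd2 (0.81 ± 0.13), asparagine synthetase Asns (0.84 ± 0.15) and the kinase-like gene Trib3 (0.80 ± 0.17). Targets of the oxidant sensor NRF2 rose as a list, with 3 of 23 called and 5 adjusted over the list alone (median 0.16, adjusted p = 7.2e-05, and adjusted p = 0.0323 with an estimated correlation), among them Gclm (0.84 ± 0.15) and Gsta3 (1.55 ± 0.29). Complement genes were lower (median -0.30, 1 of 15 called and 5 adjusted over the list alone, adjusted p = 0.000343, and adjusted p = 0.0426 with an estimated correlation). Tubulin genes had 0 of 12 called and 6 lower adjusted over the list alone (median -0.35, adjusted p = 0.000126, and adjusted p = 0.402 with an estimated correlation). The NRF2 median was 0.25 without control 1 and 0.25 with the GC trend removed, and the complement median was -0.19 without control 1 and -0.20 without Remodelin 1. Without both of these libraries the NRF2 and complement calls were lost (medians 0.08 and -0.10, adjusted p = 0.0792 and 0.0522), and the tubulin median was -0.53. All 9 genes named for these lists lost their own call without control 2 (adjusted p = 0.063 to 0.118), which for Mthfd2 and Asns was the only library to do so. Acat2, Cyp51, Insig1 and Trib3 lost it without control 3 (0.0568 to 0.121), and these 4, Mcm5 and Gsta3 without Remodelin 2 (0.0512 to 0.127). Acat2, Cyp51, Insig1, Trib3, Gclm and Gsta3 lost it without Remodelin 3 (0.051 to 0.106), Cyp51, Insig1, Trib3 and Gsta3 without control 1 (0.0523 to 0.0808), and Cyp51 and Trib3 without Remodelin 1 (0.0518 and 0.056).

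Markers of other peritoneal cells moved in the same libraries as these groups. Neutrophil markers had a median of -0.92 (2 of 7 called and 3 adjusted over the list alone, adjusted p = 0.00218, and adjusted p = 0.0498 with an estimated correlation), and B cell markers a median of -0.34 (1 of 10 called, which was also the 1 adjusted over the list alone, adjusted p = 0.00703, and adjusted p = 0.0634 with an estimated correlation). The 2 neutrophil markers called, Mmp8 and Mmp9, are also in the list of extracellular matrix remodelling genes. Mesothelial and stromal markers had a median of -0.36 and 3 of 18 called, among them Col3a1 (-1.25 ± 0.24) and Upk1b (-0.87 ± 0.18), while Krt18 stood at 1.03 ± 0.29 (adjusted p = 0.12). Adjusted over the list alone, 1 was higher and 5 were lower (adjusted p = 0.0023, and adjusted p = 0.274 with an estimated correlation), and the call was lost without Remodelin 1 (adjusted p = 0.0537). Class II presentation genes had 3 of 15 lower, namely H2-Ab1 (-0.86 ± 0.17), H2-Eb1 (-0.82 ± 0.16) and the invariant chain Cd74 (-0.67 ± 0.13), and 5 lower adjusted over the list alone. Lipid synthesis and LXR target genes had 1 of 18 lower, the same 1 adjusted over the list alone (median -0.23, adjusted p = 0.00578, and adjusted p = 0.443 with an estimated correlation). The call was lost without control 1 or Remodelin 1 (adjusted p = 0.0728 and 0.157). Dendritic cell markers had 1 of 8 lower and 2 adjusted over the list alone (median -0.31, adjusted p = 0.0271, and adjusted p = 0.12 with an estimated correlation). It was lost without control 3 (adjusted p = 0.0847) and with the GC trend removed (median -0.20, adjusted p = 0.0631). The class II list call (median -0.19, adjusted p = 0.0271, and adjusted p = 0.402 with an estimated correlation) was lost without control 2, control 3, Remodelin 2 or Remodelin 3 (adjusted p = 0.0554, 0.0813, 0.0722 and 0.0936). Its median was -0.09 without Remodelin 3 and -0.09 with the GC trend removed. The neutrophil median was -0.50, -0.53 and -0.55 without control 3, Remodelin 1 and Remodelin 2, the B cell median -0.21 and -0.17 without control 2 and Remodelin 3, the mesothelial median -0.18 and -0.15 without control 1 and Remodelin 1, and the dendritic cell median -0.48 without Remodelin 1. Without both control 1 and Remodelin 1 the mesothelial, neutrophil and lipid synthesis calls were lost at medians nearer 0 (-0.02, -0.65 and -0.13, adjusted p = 0.325, 0.0785 and 0.575). The dendritic cell call was also lost (adjusted p = 0.0792), but its median was further from 0, at -0.57, as was that of class II genes, at -0.28. Leaving out any 1 of the 4 libraries that ended the class II call also ended the calls of H2-Ab1, H2-Eb1 and Cd74 (adjusted p = 0.0571 to 0.126). Col3a1 and Upk1b lost theirs without control 1 (0.0533 for both), control 2 (0.0669 and 0.146) or Remodelin 3 (0.0567 and 0.106), and Upk1b also without Remodelin 1 or Remodelin 2 (0.0671 and 0.0599).

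With IFN-γ present, Upk3b fell by 1.57 ± 0.19 on the log2 scale, Mgp by 1.38 ± 0.20, the cell cycle inhibitor Cdkn1c by 1.05 ± 0.15 and the redox regulator Txnip by 1.03 ± 0.13, while Mthfd2 rose by 1.11 ± 0.13. These 5 and Ddit4l (-1.95 ± 0.27) were among the 7 of 25 named genes that kept the call in every fit without 1 library. Cox6a2 (1.57 ± 0.24), Vegfa (1.07 ± 0.17) and Chil1 (-2.00 ± 0.34) lost it without IFN-γ 1 (adjusted p = 0.0585, 0.0585 and 0.0943) or IFN-γ 2 (0.0731, 0.0778 and 0.0665), and Chil1 also without combined library 2 (0.0572). Losses numbered 17 without IFN-γ 2, 16 without IFN-γ 1, 11 without combined library 3, 10 without IFN-γ 3, 10 without combined library 1 and 7 without combined library 2, with adjusted p up to 0.23, 0.264, 0.17, 0.115, 0.147 and 0.0974. In all, 19 genes were higher and 30 lower. DESeq2 called 261, and the count was 11, 10 and 19 without IFN-γ 1, 2 and 3 and 26, 23 and 16 without combined libraries 1, 2 and 3. It was 271 with no filter on low counts, 358 with GC and length trends removed and 24 with the replicate block. A fit of these 2 groups alone called 83, with 21 higher and 62 lower.

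**Figure D2:**
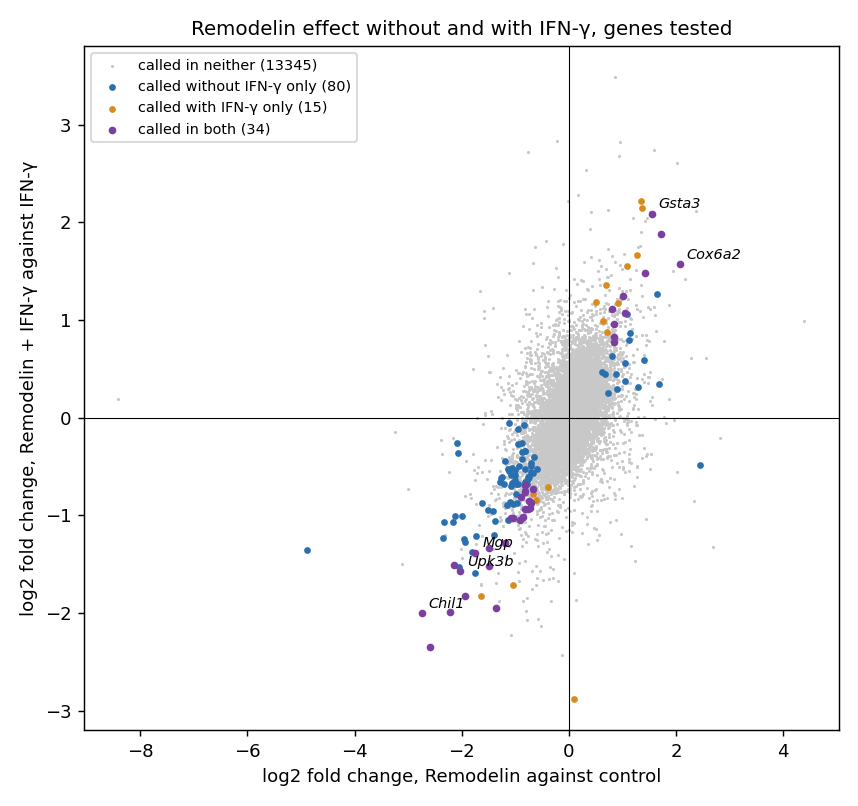
Each point is 1 of 13474 tested genes, with its log2 fold change for Remodelin against control (horizontal) and for Remodelin with IFN-γ against IFN-γ (vertical), coloured by which comparison called it. The effects had a Pearson correlation of 0.516 across genes, and 34 genes were called in both.

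Cholesterol synthesis genes were again lower, with 2 of 25 called and 17 lower adjusted over the list alone (median -0.57, adjusted p = 1.05e-12, and adjusted p = 0.00109 with an estimated correlation), including Mvd (-0.94 ± 0.16). Integrated stress response genes had 3 of 23 called and 12 higher adjusted over the list alone (median 0.45, adjusted p = 9.09e-09, and adjusted p = 0.121 with an estimated correlation), including Asns (0.96 ± 0.15) and the glutathione-degrading Chac1 (1.25 ± 0.22). Cell cycle genes were lower (median -0.31, 1 of 24 called and 4 adjusted over the list alone, adjusted p = 0.000222, and adjusted p = 0.0296 with an estimated correlation). B cell markers were at a median of -0.85, with 0 of 10 called and 4 lower adjusted over the list alone (adjusted p = 0.000287, and adjusted p = 0.033 with an estimated correlation). Class II presentation genes had 4 of 15 lower and 5 adjusted over the list alone (median -0.23, adjusted p = 0.00615, and adjusted p = 0.23 with an estimated correlation), among them H2-Ab1 (-1.01 ± 0.17) and H2-Aa (-0.78 ± 0.16). Of the genes named here, Mvd, H2-Ab1 and H2-Aa lost their own call without IFN-γ 1 (adjusted p = 0.124, 0.0762 and 0.264), and these 3, Asns and Chac1 without IFN-γ 2 (0.0731 to 0.197). Asns, Chac1 and H2-Aa lost it without IFN-γ 3 (0.068, 0.106 and 0.108), Mvd, H2-Ab1 and H2-Aa without combined library 1 (0.0691, 0.0502 and 0.0691), Chac1 and H2-Aa without combined library 2 (0.0572 and 0.0974), and Mvd, Chac1, H2-Ab1 and H2-Aa without combined library 3 (0.0541 to 0.17). Tubulin genes (median -0.43, 0 of 12 called and 8 lower adjusted over the list alone), mitochondrially encoded genes (-0.71, 0 of 12 and 5 lower) and LXR targets (-0.32, 0 of 18 and 2 lower) were lower as lists (adjusted p = 7.93e-05, 0.00205 and 0.00205, and adjusted p = 0.33, 0.452 and 0.388 with an estimated correlation). Class I processing genes had 0 of 19 called and 0 adjusted over the list alone (median -0.26, adjusted p = 0.0134, and adjusted p = 0.394 with an estimated correlation). Neutrophil markers had 1 of 7 lower, Mmp9, and 2 adjusted over the list alone (median -0.23, adjusted p = 0.0211, and adjusted p = 0.149 with an estimated correlation). It was lost without IFN-γ 2 or combined library 2 (adjusted p = 0.0853 and 0.107). NRF2 targets had 2 of 23 higher and 5 adjusted over the list alone (median 0.09, adjusted p = 0.0145, and adjusted p = 0.149 with an estimated correlation). It was lost without combined library 2 (adjusted p = 0.0616). GBP and IRG GTPases, which IFN-γ is known to induce, were higher as a list, with 0 of 9 called and 0 adjusted over the list alone (median 0.34, adjusted p = 0.0448, and adjusted p = 0.388 with an estimated correlation). That call was lost without IFN-γ 1, IFN-γ 2 or combined library 1 (adjusted p = 0.067, 0.101 and 0.364). Lysosome and TFEB targets were lower as a list, with 0 of 28 called and 0 adjusted over the list alone (median -0.16, adjusted p = 0.0211, and adjusted p = 0.23 with an estimated correlation). The call was lost without combined library 2 or 3 (adjusted p = 0.0511 and 0.0582). With the GC trend removed the GTPase and class I calls were lost (adjusted p = 0.236 and 0.114), and the medians were 0.26 for GTPases, -0.13 for class I, -0.12 for class II, -0.24 for tubulin, -0.40 for neutrophil and 0.15 for NRF2 genes. Without combined library 1 the medians were 0.17 for GTPases, -0.11 for class II genes and -0.14 for LXR targets. The neutrophil median was -0.14, -0.46 and -0.50 without IFN-γ 2, IFN-γ 3 and combined library 3, and the NRF2 median 0.14 without combined library 2. Of genes called without IFN-γ, 25 of 26 higher and 88 of 88 lower had the same sign with IFN-γ. Both comparisons called 10 genes higher, where independent lists would share 0.0367, and 24 lower, where they would share 0.196. The 2 comparisons share no library, but they share 1 fit and a trend with GC content, so lists from them are not independent. Their log2 fold changes correlated at 0.516 (Pearson), and at 0.441 with the GC trend removed. The effects of IFN-γ with and without Remodelin, which also share no library, correlated at 0.285, and at 0.129 with that trend removed.

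**Figure D3:**
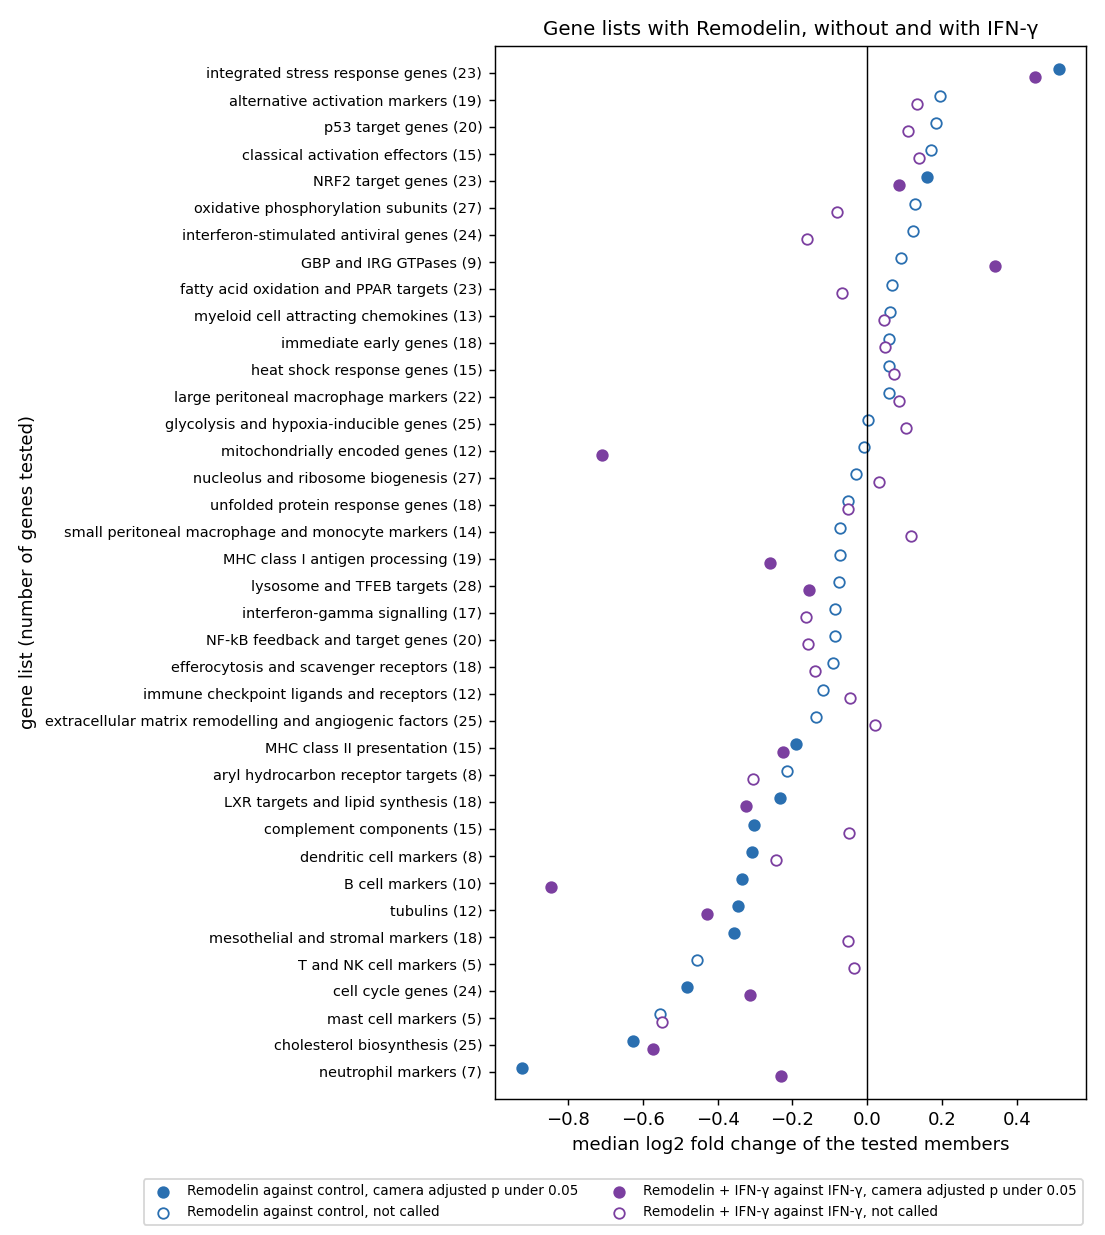
Median log2 fold change (horizontal) of 38 gene lists, with the number of tested genes in brackets, for Remodelin without (blue) and with IFN-γ (purple). Filled points passed camera at an adjusted p under 0.05, which 12 and 13 lists did, 9 of them in both.

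Averaged over both levels of IFN-γ, a comparison added after seeing the data, Remodelin raised 302 genes and lowered 647. Upk3b fell (adjusted p = 2.16e-06) and the gelatinase Mmp9 fell by 1.24 ± 0.17 on the log2 scale, while Cox6a2 rose by 1.82 ± 0.17, Chac1 by 1.13 ± 0.15 and the stress gene Ddit3 by 0.96 ± 0.16. These 5 kept their calls in each of 12 fits without 1 library, as did all 16 leading genes. Of 25 cholesterol genes 18 were lower and 21 adjusted over the list alone (adjusted p = 3.88e-16, and adjusted p = 0.000452 with an estimated correlation). Of 23 integrated stress response genes 12 were higher and 15 adjusted over the list alone (adjusted p = 7.73e-10, and adjusted p = 0.0629 with an estimated correlation). Of 24 cell cycle genes 12 were lower and 14 adjusted over the list alone (adjusted p = 4.76e-08, and adjusted p = 0.00343 with an estimated correlation), with Tk1 at -0.83 ± 0.14. The class II genes H2-Ab1 (-0.94 ± 0.12) and H2-Eb1 (-0.88 ± 0.11), the complement genes C1qa (-0.72 ± 0.12) and C1qb (-0.62 ± 0.13) and the chemokine Cxcl10 (-1.47 ± 0.25, adjusted p = 0.00297) fell. As lists, class II presentation had 6 of 15 lower, with 2 higher and 6 lower adjusted over the list alone (median -0.22, adjusted p = 0.0136, and adjusted p = 0.288 with an estimated correlation), and complement 5 of 15 lower and 6 adjusted over the list alone (median -0.13, adjusted p = 0.00527, and adjusted p = 0.0766 with an estimated correlation). The class II median was -0.11 with the GC trend removed, and the complement median -0.06 without both control 1 and Remodelin 1. Markers of other cells moved in the same comparison. B cell markers had 3 of 10 lower and 3 adjusted over the list alone (median -0.48, adjusted p = 0.000505, and adjusted p = 0.0398 with an estimated correlation), and neutrophil markers 2 of 7 and 3 (median -0.58, adjusted p = 0.00523, and adjusted p = 0.0629 with an estimated correlation). The 2 neutrophil markers called, Mmp8 and Mmp9, are also in the list of extracellular matrix remodelling genes. Dendritic cell markers had 2 of 8 lower and 2 adjusted over the list alone (median -0.23, adjusted p = 0.0456, and adjusted p = 0.169 with an estimated correlation). The call was lost without control 1, control 3, IFN-γ 1, IFN-γ 3 or combined library 3 (adjusted p = 0.0508, 0.0754, 0.0547, 0.0647 and 0.0743). Mesothelial and stromal markers had 4 of 18 lower, and 1 higher and 5 lower adjusted over the list alone (median -0.16, adjusted p = 0.0456, and adjusted p = 0.354 with an estimated correlation). It was lost without control 1, IFN-γ 3 or Remodelin 1 (adjusted p = 0.125, 0.084 and 0.148), and its median was -0.10 without control 1. The B cell median was -0.31 without control 2, and the neutrophil median -0.35, -0.37 and -0.35 without IFN-γ 2, Remodelin 1 and combined library 1. With the GC trend removed the dendritic cell call was lost (median -0.10, adjusted p = 0.106). Without both control 1 and Remodelin 1 the mesothelial call was lost at a median of -0.07 (adjusted p = 0.352), and the dendritic cell call at a median further from 0, of -0.31 (adjusted p = 0.0664). Log2 fold changes of this comparison had a Spearman correlation of -0.50 with GC content. The trend was not particular to it. That correlation was -0.51 to -0.43 in the 4 comparisons between groups, -0.58 for the average IFN-γ effect and -0.09 for the interaction. Removal of the GC trend gave 768 calls, and only 574 of the 949 were among them. The share of lower calls was 68.2%, against 61.1% of those 768 calls and 55.4% of 1515 calls after removal of GC and length trends. The excess of lower calls was absent with no filter on low counts, at 778 higher and 628 lower (44.7% lower), and without both control 1 and Remodelin 1, at 1849 higher and 1819 lower (49.6%). DESeq2 gave 604 higher and 774 lower (56.2%). The count was 298 without control 2, 533 without control 3, 310 without IFN-γ 1, 373 without IFN-γ 2, 552 without IFN-γ 3, 561 without Remodelin 2, 428 without Remodelin 3, and 555 and 625 without combined libraries 1 and 3. It was 1739 without control 1, 1960 without Remodelin 1 and 3668 without both.

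Few genes were called with IFN-γ alone, in a test that recovered 41.8% of simulated 2-fold and 14.9% of 1.5-fold changes. The transcription factor Irf1, central to the response to this cytokine, stood at a log2 fold change of 0.12 ± 0.17. The GTPases Gbp2 and Irgm1 were at 0.30 ± 0.17 and 0.39 ± 0.23, the checkpoint ligand Cd274 at 0.14 ± 0.16 and the class II activator Ciita at -0.72 ± 0.43, and none of the 5 was called. The 95% interval of Irf1 ran from -0.24 to 0.49. Cxcl9, another target, had 5 reads over all 12 libraries and Nos2 had 0, which allows up to 0.188 CPM in the shallowest library. Ifit1, an antiviral gene, was at 2.12 ± 0.50 (adjusted p = 0.568). GBP and IRG GTPases had a median of 0.06 with 0 of 9 called and 0 adjusted over the list alone (adjusted p = 0.783). IFN-γ signalling genes were at 0.08 with 0 of 17 and 0 (adjusted p = 0.748). Class I processing genes were at 0.05 with 0 of 19 and 0, while their mean was -0.02 (adjusted p = 0.72). Antiviral interferon-stimulated genes had a median of 0.18, with 0 of 24 called and 1 higher adjusted over the list alone (adjusted p = 0.0246, and adjusted p = 0.52 with an estimated correlation). That call was lost without control 2, control 3, IFN-γ 1 or IFN-γ 2 (adjusted p = 0.0551, 0.0645, 0.0773 and 0.0506). Mitochondrially encoded genes were higher as a list, with 0 of 12 called and 1 higher adjusted over the list alone (median 0.70, adjusted p = 4.42e-09, and adjusted p = 0.52 with an estimated correlation). That median was 1.22 without control 2, 0.41 without control 3 and 0.30 with the GC trend removed. Lower as lists, with 0 members called and 0 adjusted over the list alone, were 23 integrated stress response genes (median -0.19, adjusted p = 0.0044), 18 immediate early genes (-0.19, adjusted p = 0.00751) and 18 mesothelial and stromal markers (-0.27, adjusted p = 0.0394). None of these 3 held, at adjusted p = 0.52, 0.52 and 0.595 with an estimated correlation. The first was lost without control 2 (adjusted p = 0.06), the second without control 1 or IFN-γ 1 (0.0537 and 0.05), and the mesothelial call without control 1, control 2, IFN-γ 1 or IFN-γ 2 (0.194, 0.162, 0.114 and 0.11). With the GC trend removed all 3 were lost (medians -0.10, -0.12 and -0.17, adjusted p = 0.119, 0.396 and 0.0598), and the antiviral median was 0.11. Without 1 library the antiviral median was 0.11 (control 3) and 0.27 (IFN-γ 1), the stress response median -0.13 (control 2), and the immediate early median -0.11 (control 1) and -0.12 (IFN-γ 2). Of 13474 genes 2 were called, both higher, and 724 had an unadjusted p under 0.05 where chance alone gives 673.7. DESeq2 called 4, limma-voom 1, a fit of these 2 groups alone 19 and a fit with no filter on low counts 52, with 38 higher and 14 lower. The called genes were mt-Tp, which lies between other mitochondrial transcripts and is uncertain as the strand setting is not given, from 6.11 ± 2.76 to 55.8 ± 6.58 CPM (log2 fold change 3.19 ± 0.33, adjusted p = 0.000304), and the predicted gene Gm17066 (2.11 ± 0.33, adjusted p = 0.0488), named after its values were seen. The count was 1 without any 1 library of either group except IFN-γ 2, where it was 2. In each of these fits mt-Tp kept its call and Gm17066 lost it.

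**Figure D4:**
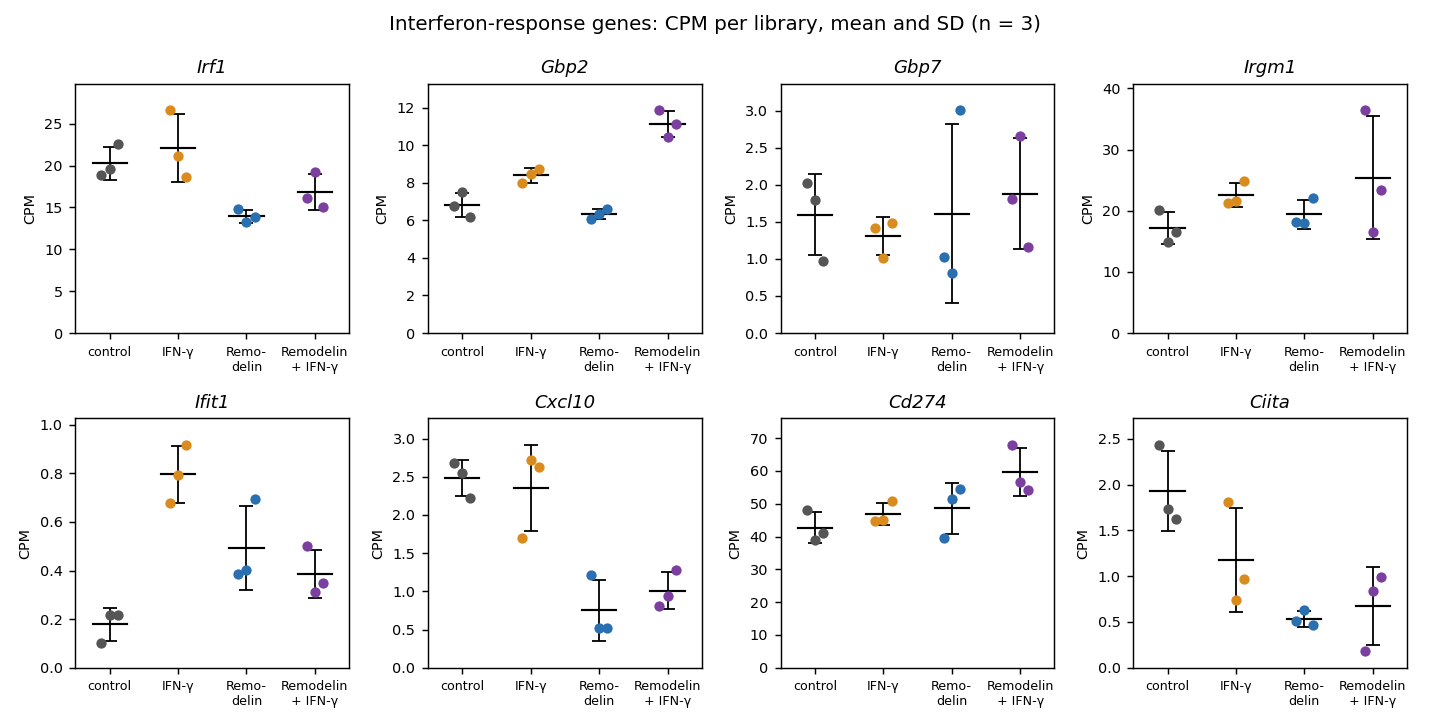
CPM of 8 interferon-response genes in each library (points), by group on the horizontal axis, with the mean and SD of 3 libraries (black). Irf1 was at 20.3 CPM in control and 22.1 CPM in IFN-γ libraries, and Cd274 at 42.7 and 46.9 CPM.

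IFN-γ in the presence of Remodelin called 0 genes by edgeR, with 1043 at an unadjusted p under 0.05, 1 call by DESeq2 and 0 by limma-voom. Gbp2 was at 0.81 ± 0.17 (adjusted p = 0.636) and Irf1 at 0.27 ± 0.18. GBP and IRG GTPases had a median of 0.39, with 0 of 9 called and 1 higher adjusted over the list alone (adjusted p = 0.0142, and adjusted p = 0.842 with an estimated correlation). The call was lost without Remodelin 2 or combined library 1 (adjusted p = 0.126 and 0.158). Integrated stress response genes were lower as a list, with 0 of 23 called and 1 lower adjusted over the list alone (median -0.11, adjusted p = 0.0142, and adjusted p = 0.842 with an estimated correlation). It was lost without Remodelin 1, Remodelin 2 or combined library 1 (adjusted p = 0.202, 0.069 and 0.078). Immediate early genes had 0 of 18 called and 0 adjusted over the list alone (median -0.15, adjusted p = 0.0436, and adjusted p = 0.842 with an estimated correlation). The call was lost without Remodelin 2, Remodelin 3 or combined library 1 (adjusted p = 0.262, 0.055 and 0.192). All 3 calls were lost with the GC trend removed (medians 0.21, -0.07 and -0.04, adjusted p = 0.167, 0.38 and 0.89). The GTPase median was 0.07 without combined library 1, the stress response median -0.07 without Remodelin 1, and the immediate early median -0.09 and -0.08 without Remodelin 2 and combined library 1. Averaged over both levels of Remodelin, integrated stress response genes were lower (median -0.14, 0 of 23 called and 1 adjusted over the list alone, adjusted p = 0.000572), immediate early genes lower (-0.17, 0 of 18 and 0, adjusted p = 0.00217) and mitochondrially encoded genes higher (0.43, 0 of 12 and 3, adjusted p = 0.000102). With an estimated correlation all 3 were at an adjusted p = 0.789, and with the GC trend removed they were at medians of -0.08, -0.04 and 0.15 (adjusted p = 0.223, 0.606 and 0.358). The mitochondrial median was 0.71 without control 2 and 0.26 without control 3. For this average 1735 genes had an unadjusted p under 0.05, where chance alone gives 673.7. With the GC trend removed 1002 did. The test of whether the response to IFN-γ differed with Remodelin called 1 gene, mt-Tp (log2 -2.92 ± 0.44, adjusted p = 0.0481). That call was lost without control 2, control 3, IFN-γ 1, 2 or 3, Remodelin 2, Remodelin 3 or combined library 1 (adjusted p = 0.38, 0.131, 0.125, 0.221, 0.138, 0.16, 0.0593 and 0.313). Removal of the GC trend, removal of GC and length trends and the filter of 50 reads in 3 libraries also left 0 genes. Since mt-Tp was called higher than control with IFN-γ alone and with Remodelin alone, low values in control libraries enter this difference. The set of genes responsive to IFN-γ on average held only mt-Tp, so overlap with the Remodelin calls could not be studied.

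The authors' deposited table was read at an adjusted p under 0.05. It called 129 genes for Remodelin against control, 40 higher and 89 lower, of which 99 were among the 114 found here. For Remodelin with IFN-γ against IFN-γ it called 591, with 32 shared, and for IFN-γ against control 122, with 1 shared. It held values for 20551, 20435 and 20578 genes in that order, against 13474 tested here, so the sets of genes differ. In the same order a fit here with no count filter called 283, 271 and 52, and DESeq2 called 267, 261 and 4.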

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

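Every test of an explanation in this part, and every fit of lists without libraries or the GC trend, was chosen after the result was seen, except the regroupings of the samples, and the average Remodelin effect itself was added after seeing the data. The interaction picked out 6 results, those where the response to IFN-γ differed between cells with and without Remodelin. They were mt-Tp (log2 -2.92) and the medians of mitochondrially encoded genes (-0.476), oxidative phosphorylation subunits (-0.234), mesothelial and stromal markers (0.356), cell cycle genes (0.181) and GBP and IRG GTPases (0.361). All 5 lists lost their call with an estimated correlation (adjusted p = 0.739, 0.81, 0.739, 0.362 and 0.739). Leaving out 1 library ended the call of mitochondrially encoded genes without Remodelin 3 (adjusted p = 0.0789). The oxidative phosphorylation call ended without control 1, IFN-γ 2, Remodelin 1, or combined library 2 or 3 (0.755, 0.124, 0.964, 0.254 and 0.133). The mesothelial call ended without control 1 or 2, IFN-γ 2, Remodelin 1 or 3, or combined library 2 or 3 (0.0709, 0.0807, 0.0685, 0.207, 0.0505, 0.187 and 0.133). The cell cycle call ended without control 2, IFN-γ 2, Remodelin 2 or 3, or combined library 1 or 3 (0.135, 0.0685, 0.125, 0.121, 0.105 and 0.133). The GTPase call ended without control 1 or 2, IFN-γ 1 or 2, Remodelin 1 or 2, or combined library 1 (0.0617, 0.0807, 0.0519, 0.124, 0.0704, 0.19 and 0.513), and also with the GC trend removed (0.07, median 0.30). Without control 1 and Remodelin 1 together the GTPase, mesothelial and oxidative phosphorylation calls ended (0.285, 0.499 and 0.378), at medians of 0.30, 0.17 and 0.13. The mitochondrial median was -1.07 without control 2, -0.23 without control 3, -0.29 without Remodelin 3 and -0.24 with the GC trend removed. That of oxidative phosphorylation was -0.10, -0.14 and 0.01 without control 1, IFN-γ 2 and Remodelin 1, that of GTPases 0.19 without Remodelin 2, and that of mesothelial markers 0.53 without combined library 1. Regrouping gave 9 genes for the interaction against the real 1, and 9 against 1 for the average IFN-γ effect, with 14 and 12 of 100 regroupings as large, so chance cannot be excluded for either.

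In IFN-γ against control, 3 lists of the cytokine's target and signalling genes were not called. Antiviral genes were higher as a list there, with Ifit1 at 2.12 ± 0.50 (adjusted p = 0.568, 0.179 CPM in control and 0.796 CPM in IFN-γ libraries), as GBP and IRG GTPases were under Remodelin, but both calls were lost with an estimated correlation (adjusted p = 0.52 and 0.842) and without single libraries, the first without control 2, control 3, IFN-γ 1 or IFN-γ 2 (0.0551, 0.0645, 0.0773 and 0.0506) and the second without Remodelin 2 or combined library 1 (0.126 and 0.158). For the 3 lists, too few libraries to show a doubling is argued against, since 97.8% of their 45 tested members, 44 genes, had an upper 95% bound under it. The signalling list, 17 of these members, also holds receptors and kinases that need not rise, so that share overstates the case. Only 1 of the 45 lay over the bound, so the GTPase and class I lists hold no more than 1 such gene. This leaves open a smaller rise and the antiviral genes outside these lists, as the test recovered only 41.8% of simulated 2-fold changes. Exchanged labels are argued against, since the mean log2 CPM of these lists ranged over only 0.156 across all 12 libraries, and missing receptor and signalling transcripts likewise, since the lowest of 5 such genes, Jak2, was at 5.86 CPM or more in every library. The activity, dose and time of the cytokine stay open, as they were not measured.

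Averaged over both levels of IFN-γ, cholesterol genes were lower and integrated stress response genes higher with Remodelin, the second with a call lost at an adjusted p = 0.0629 with an estimated correlation. A GC trend between libraries is argued against, since with it removed the larger adjusted p of the 2 lists was 0.000778 with an estimated correlation, and a transcript length trend likewise, at 0.0017 with both trends removed. An exchange of control 1 and Remodelin 1 is argued against, since Remodelin 1 scored 1.89 above the highest control over genes called in the comparison with IFN-γ. The fold changes of that comparison use neither library, but its calls used a spread estimated with both under their given labels. A change of cell composition stays open, since B cell markers (median -0.48, adjusted p = 0.000505, and adjusted p = 0.0398 with an estimated correlation) and neutrophil markers (median -0.58, adjusted p = 0.00523, and adjusted p = 0.0629 with an estimated correlation) fell in the same comparison. The called neutrophil markers were Mmp8 and Mmp9, which are also in the list of extracellular matrix remodelling genes, so their fall need not reflect neutrophils. A loss of other cells as the source of the stress response rise would raise macrophage markers as much. Of 22 such markers, 14 had an upper 95% bound under its median of 0.57, and the intervals of 8 included it. The marker median was 0.05. The share set for a verdict was not reached, so this stays short of a verdict. The 14 markers and the marker median argue against that loss as the whole source of the rise. Of the 25 listed markers 7 are also in other lists, so some may change on their own. A smaller part stays open. For cholesterol genes composition was not tested, so an effect of Remodelin within macrophages is 1 of the open explanations.

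Upk3b fell with Remodelin, averaged over both levels of IFN-γ. Fewer mesothelial cells as the whole cause is argued against, since the 95% intervals of all 8 other mesothelial markers lay wholly above that of Upk3b. They went both ways, with Upk1b (-0.56 ± 0.13, adjusted p = 0.0146) and Krt19 (-0.71 ± 0.21, adjusted p = 0.0483) lower, and Msln, Krt8 and Krt18 at 0.64, 0.43 and 0.61 without a call (adjusted p = 0.188, 0.122 and 0.0758), so a smaller loss stays open as part of it. A GC trend is argued against, since with it removed the log2 fold change was -1.67. A change of this gene within macrophages or within mesothelial cells was not tested.

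The 10 splits of the 6 libraries of Remodelin against control are too few for a share under 0.05, with 114 genes for the real split and 2505 for the highest other. The same holds for IFN-γ against control (2 against 0), Remodelin with IFN-γ against IFN-γ (49 against 1) and IFN-γ with Remodelin (0 against 3). The split with 2505 genes exchanges control 1 and Remodelin 1, which points to a structure of the samples. It parts libraries whose deviations correlate positively with transcript length (control 1 at 0.46, Remodelin 2 at 0.392, Remodelin 3 at 0.34) from those with negative values (-0.173, -0.292 and -0.473). For the lists of the average Remodelin effect no other of the 100 regroupings gave as many as the real 13, with 11 as the highest. That share is under 0.05, but it holds only for the preset correlation. With an estimated correlation 3 lists were called, and regroupings were not run at that setting. For the genes of this effect 4 of 100 regroupings gave as many, the real one included. That is a share under 0.05, but 1 of them called 1864 against 949. That regrouping exchanges control 1 and Remodelin 1 among others, so the gene count carries the same structure of the samples.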

How the results depend on the processing

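Removal of GC or length trends, leaving out 2 libraries together, every alternative of both average effects, and leave-one-out fits of lists were chosen after seeing the data. No called named gene changed direction. The oxidative phosphorylation list of the interaction turned direction without control 1 and Remodelin 1 (adjusted p = 0.378). The cause of each change below was not tested. Fits of fewer libraries hold less information, but this does not explain the rises in such fits. The average Remodelin count rose to 1739 without control 1, 1960 without Remodelin 1 and 3668 without both. Counts of called genes moved as follows. IFN-γ against control (2) gave 1 with DESeq2 size factors, 52 without a filter, 1 with the strict filter, 4 with DESeq2, 1 with limma-voom, 1 with GC and 1 with GC and length removed, 19 with 2 groups, and 1 to 2 without 1 library. Remodelin against control (114) gave 283 without a filter, 267 with DESeq2, 190 and 408 with GC and with GC and length removed, 22 with 2 groups, 1853 without control 1 and Remodelin 1, and 20 to 121 without 1 library. Remodelin with IFN-γ against IFN-γ (49) gave 271, 261, 358 with GC and length removed, 83 with 2 groups, and 10 to 26. IFN-γ with Remodelin (0) gave 6 without a filter and 1 with DESeq2, and 0 without any 1 library. The interaction (1) gave 19 without a filter, 0 with the strict filter, 0 with GC and 0 with GC and length removed, and 0 to 1. The average IFN-γ effect (1) gave 325, 23 and 0 without a filter, with DESeq2 and with GC and length removed, and 0 to 4. The average Remodelin effect (949) gave 1515 with GC and length removed, 3668 without both libraries, and 298 to 1960. The responsive set (1) gave 2 when chosen on IFN-γ against control, and 0 to 3. The correlation of Remodelin effects (0.516) was 0.683 with the strict filter and 0.356 to 0.513 without 1 library. Counts of called lists with an estimated correlation, then also with GC, then also with GC and length removed, were 0, 0 and 0 for IFN-γ against control (5, and 3 with GC removed alone), 5, 6 and 4 for Remodelin (12), 3, 5 and 5 with IFN-γ (13), 0, 0 and 0 for IFN-γ with Remodelin (3, and 0 with GC removed alone), 0, 0 and 0 for the interaction (5, and 2 without both libraries), 0, 0 and 0 for average IFN-γ (3, and 0 with GC removed alone) and 3, 7 and 5 for average Remodelin (13). Without 1 library they ran 2 to 6, 10 to 13, 10 to 15, 0 to 4, 1 to 6, 3 to 6 and 11 to 15. With the replicate number as a block, the counts were 1, 58, 24 and 578 for IFN-γ, Remodelin, Remodelin with IFN-γ and average Remodelin. The numbers showed no pairing of the libraries. Only 5 of 18 same-number pairs correlated above 0.1 (-0.547 to 0.261), and 2 of 12 libraries correlated best with their own number. The check cannot exclude pairing, since library trends with transcript length enter these correlations. The lowest pair, control 1 and Remodelin 1, had length correlations of 0.46 and -0.473. At this depth and spread, simulated 1.5-fold changes were recovered in 8.96% of genes for Remodelin against control.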

Other observations

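The average effect, all its alternatives and the test of an explanation in this part were chosen after the result was seen. Averaged over both levels of IFN-γ, other gene groups moved with Remodelin. Of 12 tubulin genes 6 were lower and 8 adjusted over the list alone (median -0.38, camera adjusted p = 2.71e-05, and adjusted p = 0.296 with an estimated correlation), with Tubb3 at -0.94 ± 0.16 and Tuba1a at -0.75 ± 0.13. Of 18 lipid synthesis and LXR target genes 4 were lower and 7 adjusted over the list alone (median -0.30, adjusted p = 0.000979, and adjusted p = 0.354 with an estimated correlation), with Fads2 at -0.83 ± 0.13. The LXR median was -0.19 without combined library 1, and its call was lost without both control 1 and Remodelin 1 (median -0.25, adjusted p = 0.0602). Of 23 NRF2 targets 6 were higher and 6 adjusted over the list alone (median 0.13, adjusted p = 0.00074, and adjusted p = 0.0561 with an estimated correlation), with Gsta3 at 1.82 ± 0.22 and catalase, Cat, at 0.58 ± 0.11. With the GC trend removed the tubulin median was -0.22 and the NRF2 median 0.21, and without both control 1 and Remodelin 1 the NRF2 median was 0.08. Lysosome and TFEB targets had 3 of 28 lower and 9 adjusted over the list alone (median -0.13, adjusted p = 0.0365, and adjusted p = 0.269 with an estimated correlation), a call lost without combined library 3 (adjusted p = 0.0661). Single genes that rose included the cell cycle inhibitor Cdkn1a (0.54 ± 0.10), the phosphatase Dusp1 (0.63 ± 0.11) and the collagenase Mmp13 (1.07 ± 0.23), and the efferocytosis bridge Mfge8 fell by 0.79 ± 0.13. These genes kept their calls in each of 12 fits without 1 library.

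Macrophage identity and activation lists did not pass in the same comparison. Large peritoneal macrophage markers had a median of 0.05 (1 of 22 called, adjusted p = 0.824), with Gata6, the factor that defines these cells, at -0.12 ± 0.16. Alternative activation markers were at 0.16 (2 higher and 1 lower of 19, adjusted p = 0.309), with Arg1 at 0.32 ± 0.13 and Mrc1 at 0.09 ± 0.15. Classical activation effectors had a median of 0.09 and a mean of -0.03 (adjusted p = 0.809), and checkpoint genes were at -0.11 (adjusted p = 0.637), with Cd274 at 0.27 ± 0.11. Nucleolar and ribosome biogenesis genes, the compartment of NAT10, were at -0.05 (1 higher and 1 lower of 27, adjusted p = 0.633).

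A hypothesis was that integrated stress response genes rose through stress of the endoplasmic reticulum, which could be expected to raise chaperones of the unfolded protein response as well. The upper 95% bounds of all 18 such genes lay under 0.57, the median of the stress response list, and their own median was -0.03. This argues against that route as the source of the whole change, and other routes to ATF4 were not tested.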
